A study of Drosophila melanogaster with 2 samples.

How the data were processed

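The samples were 2 biological replicates, per the labels, of 1 line of Drosophila melanogaster that expresses Hnf4 with a C-terminal green fluorescent protein. Chromatin of whole larvae at the wandering stage of the third instar, sheared by sonication per the labels, was precipitated with an antibody against that protein per the labels' description, while their antibody field names Hnf4. The authors deposited 8 region lists used here, 4 per genome build (dm6 and dm3): a relaxed list for each replicate, a relaxed list of the replicates pooled, and an optimal list. Relaxed lists hold strong regions and background and serve as input for the irreproducible discovery rate, which ranks regions by how well replicates match. The optimal list came from both replicate lists and the pooled list, and both replicates were set against the same control, per the deposited file descriptions. The aligner, the peak caller and their versions are not given in the sources used here.

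The deposited file descriptions name the narrowPeak format, in which each region has a signal value for its enrichment. The authors' signal values were used to rank and describe regions within a list and, in the permutation tests, to compare peaks with and without a motif within the optimal list. Each also has a -log10 q, deposited by the authors as that format defines it, which was read and not tested. Summits were taken from the deposited offset within each region. Read counts per replicate are in none of these lists, so the depth is unknown and no interval that needs it was computed. Exact binomial intervals are on numbers of peaks or genes. Levels were compared between lists for replicate 1 alone, where the highest mitochondrial and the median signal value in dm3 were set against those in dm6.

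Positions are in dm6, 1-based. All dm6 regions lay within the chromosome lengths of the Release 6 reference, whose sequence was used for motifs, and protein-coding genes and transcripts came from Ensembl release 115 (13981 genes with 19643 TSSs). No coordinates were converted between builds, and dm3 lists entered counts, chromosome shares, overlaps of dm3 with dm3 and that comparison of signal values. A summit within 1000 bp of a TSS was called promoter, and otherwise exon, intron or intergenic in that order. The background for peaks was the 23100 relaxed pooled regions that overlapped no optimal peak, and for genes the 5798 with a relaxed summit at a promoter. Motifs were searched on both strands within 100 bp of summits.

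Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family. Overlap of replicates was tested with 1000 seeded circular shifts, and the relation of motifs to signal with 100000 permutations for the 10 motifs at 10 or more peaks. The tests, gene lists, motifs and most alternatives were fixed before the data were examined. Of the listed genes, Pex11, ABCD, Tor and nos were not matched to the annotation and were left out. Signal tracks that the deposited file descriptions also list were not used here. Named genes followed a rule fixed in advance: the first 20 genes within 5000 bp of the strongest peaks supported by both replicates, up to 4 members of each list with the strongest promoter peak and up to 2 without a peak in alphabetical order, Hnf4, and all candidate targets. Members were left out for lists given as a count with 1 example, and 1 gene that the rule gives is not reported here. Alternatives were other TSS and summit windows, stricter peak sets, each replicate alone, other backgrounds, a logistic model with TSS number as a covariate, motifs split by promoter location, and the dm3 lists. The covariate model used a likelihood ratio test, which rests on a chi-square approximation, in place of a Wald test that was run first and is reported too.

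The tests were tried on simulated data. With no motif planted, 0 of 8192 sequences of 7 bases were called. Both simulated sets came at random from the background regions, so differences in promoter share or base composition were not simulated. The real optimal and background sets differ in both, with promoter shares of 53.8% and 27.2% and G and C content of 37.8% and 36.1%. A sequence planted in 3% of 5000 regions ranked first. CAAAGTC, part of the Hnf4 site CAAAGTCCA, was planted in 1%, reached an adjusted p of 0.144 by Fisher's exact test and was not called. In that run 2 sequences were called, including the sequence planted in 3%, and the one planted in 1% was number 3. With gene lists, 2 of 2100 tests with no effect were called, and fatty acid oxidation with a peak at 90% of members was called in 83 of 100 draws. The logistic model called 2 of 420 tests with no effect and that list in 15 of 20 draws. Genes were drawn independently of each other, so peaks shared by neighbouring genes were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.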

Results

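Chromatin immunoprecipitation with sequencing was used to map where Hnf4 sits on the genome of Drosophila melanogaster larvae. Hnf4 is a nuclear receptor, a class of transcription factors that includes receptors for hormones and lipids, and its vertebrate relatives act in liver metabolism. The flies carried Hnf4 fused to green fluorescent protein, and chromatin from whole larvae of both sexes, at the third instar's wandering stage, was precipitated with an antibody against that protein, per the labels' description. The antibody field of the labels names Hnf4 instead, so whether untagged Hnf4 was also precipitated is not settled. The samples form 1 group of 2 biological replicates, so there is no contrast between conditions, and the comparisons below are between replicates and between strong and weak regions. The files used here hold called regions and no read counts, so the sequencing depth of each replicate is unknown.

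The authors' optimal set held 5817 peaks in the dm6 build, with a median width of 396 bp. Their signal values, the authors' own measure of enrichment for each region, ran from 66.6 to 3161 with a median of 114. The set was the same as the 5817 strongest entries of the relaxed list called on both replicates pooled, which had 30000 entries. In dm3, an older build, the optimal set held 5711 peaks. Of the dm6 peaks, 56 repeated the interval of another peak with a different summit.

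Both replicates marked largely the same places. Of the 5817 strongest regions of replicate 1, 73.0% overlapped one of the 5817 strongest of replicate 2 by at least 1 bp. Circular shifts of the replicate 2 regions along each chromosome gave 2.80% on average and 4.45% at most (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Among the optimal peaks, 99.5% overlapped some region of replicate 1 and 97.6% some region of replicate 2, while 4130 peaks, or 71.0%, overlapped the strongest regions of both. Across the 5651 peaks with a value in each replicate, Spearman's rho of the signal values was 0.70 and Pearson's r of their log2 values was 0.78. These correlations are across peaks, which are not independent replicates. The optimal set was derived from these same replicates, so its overlaps with them and these correlations are in part built in.

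**Figure D1:**
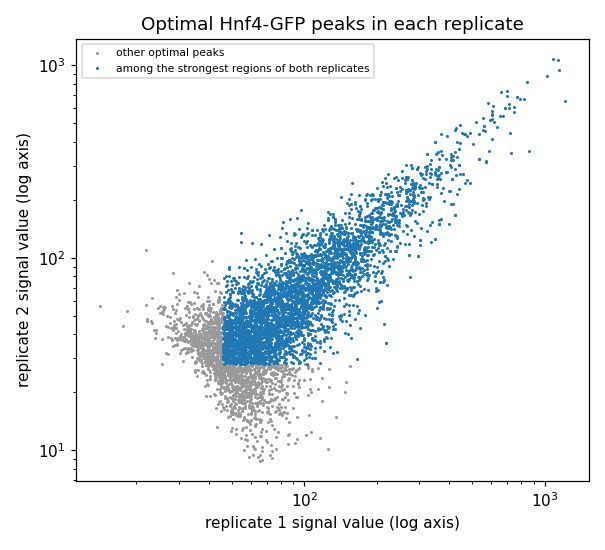
Signal values of the optimal peaks in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), 1 point per peak with a region in both. The 4130 peaks among the strongest regions of both replicates are in blue and the others in grey, and peaks high in one replicate were mostly high in the other (Spearman's rho 0.70).

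The strongest peaks supported by both replicates lay at a mixed set of genes. The first was near cbt (FBgn0043364), which encodes a zinc finger transcription factor, at chromosome 2L 480574 to 481411, with its summit 1413 bp upstream of the cbt transcription start site (TSS) and inside the larger gene ush. Its signal value was 2177, with 1137 in replicate 1 and 1074 in replicate 2. The next were CG14100 at 2159, CG11050 at 2085 and Ugalt, a UDP-galactose transporter gene, at 1883. Among the first 20 genes were mRpS10 at 1227 and mRpL41 at 1222, which encode mitochondrial ribosomal proteins, and PNPase, a mitochondrial RNA-processing enzyme gene, at 1342. The list also held Lk6 at 1311, ph-p at 1266, larp at 1195 and Chro at 1157. The gene yip2 (FBgn0040064), which encodes an enzyme of fatty acid beta-oxidation, was there too, with a peak at 2L 9914993 to 9915700 of signal value 1227. The remaining genes were CG1888, CenG1A, CG32772, Tcs5, CG8320, CG31668, CG43245 and CG18549, with signal values from 1170 for CG18549 to 1615 for CG1888.

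Optimal peaks lay at promoters more often than weaker regions did. Summits within 1000 bp of the TSS of a protein-coding transcript made up 53.8% of optimal peaks (95% exact interval 52.5 to 55.1) and 27.2% of the 23100 relaxed regions outside the optimal set (26.6 to 27.8). Introns held 30.2% against 45.0%, other exon positions 1.07% against 7.44%, and intergenic positions 14.9% against 20.4%. Fisher's exact test, two-sided, gave an odds ratio of 3.12 for promoters (adjusted p = 2.96e-310 over 4 classes), and each of the other classes was lower in the optimal set, with adjusted p from 9.08e-100 to 4.90e-22. Neighbouring peaks are not independent, so these p-values are too small by an unknown amount.

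The Hnf4 site CAAAGTCCA was found near more optimal summits than weak ones, but near few of either. It occurred within 100 bp of 61 of the 5817 optimal summits, or 1.05%, against 0.372% of weaker regions (odds ratio 2.84, Fisher's exact test, adjusted p = 8.84e-09 over 12 motifs). The wider direct repeat RGKNCAAAGKNCA, a sequence with 1 base between its repeats, occurred in 0.705% against 0.208% (odds ratio 3.41, Fisher's exact test, adjusted p = 7.78e-08). The same site written backwards, ACCTGAAAC, which served as a control, occurred in 0.138% against 0.104% (exact test, adjusted p = 0.676). Of 129 Hnf4 sites within 500 bp of optimal summits, 43 lay within 50 bp.

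Some shorter motifs were found at a larger share of the same peaks than the Hnf4 site, but also at a larger share of weaker regions. Their shares are thus not a measure of relative importance, and the odds ratio of the Hnf4 site was 2.84. The DNA replication-related element TATCGATA, found at promoters of many growth genes, occurred at 4.04% of optimal peaks against 1.05% (odds ratio 3.98, Fisher's exact test, adjusted p = 1.53e-45). The M1BP site GGTCACAC occurred at 2.10% against 0.697% (odds ratio 3.05, exact test, adjusted p = 5.47e-18). GAGAGAG, bound by GAGA factor, was at 352 optimal peaks, or 6.05%, against 739 of the 23100 weaker regions (odds ratio 1.95, exact test, adjusted p = 3.33e-21). The GATA site AGATAAG was less frequent in optimal peaks, at 2.92% against 3.85% (exact test, adjusted p = 0.00134). In a split chosen after the data were seen, 3 of these differences were not found outside promoters by Fisher's exact test. There, TATCGATA was at 0.484% against 0.630% (odds ratio 0.766, exact test, adjusted p = 0.599), the M1BP site at 0.409% against 0.285% (exact test, adjusted p = 0.517) and the GATA site at 3.28% against 3.68% (exact test, adjusted p = 0.544). The Hnf4 site was more frequent both at promoters (0.958% against 0.270%, odds ratio 3.57) and outside them (1.15% against 0.410%, odds ratio 2.83). The E-box, ecdysone response, FOXO, CREB and C/EBP motifs did not pass the test, with adjusted p from 0.0649 for FOXO to 1. Of all 8192 sequences of 7 bases, 638 were more frequent and 292 less frequent in optimal peaks at an adjusted p under 0.05. The first was ACTATCG, at 4.85% against 1.07%. AAGTCCA, part of the Hnf4 site, was number 209 (3.64% against 2.48%, exact test, adjusted p = 9.59e-05). Of the other parts of the site, AAAGTCC was number 865 (exact test, adjusted p = 0.0417) and CAAAGTC, at 4.04% against 3.46%, was number 1740 and not called (exact test, adjusted p = 0.171). In the simulation CAAAGTC planted in 1% of regions was not called either. The scan can thus miss a difference of that size, and these ranks do not show how much the Hnf4 site contributes.

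Peak strength was compared between peaks with and without each motif. Peaks with CAAAGTCCA had a median signal value of 108 against 114 without it (permutation test, two-sided, adjusted p = 0.806 over 10 motifs). Peaks with the direct repeat had a median of 233 against 114 without it (permutation test, two-sided, adjusted p = 0.0001), with 1 of the 41 in the weakest quartile of signal and 22 in the strongest. The unadjusted p of 1e-05 is the smallest that 100000 permutations can give. Whether these trends differ from each other was not tested.

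**Figure D2:**
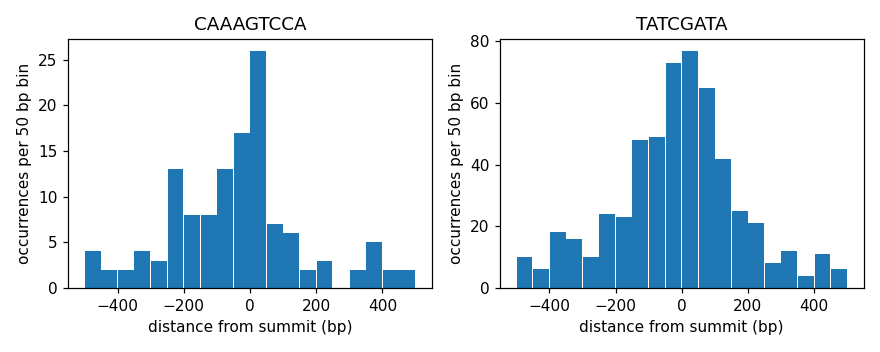
Occurrences of the Hnf4 site CAAAGTCCA (left) and of TATCGATA (right) by distance from the summits of optimal peaks, in bins of 50 bp, both strands counted. Within 50 bp of summits lay 43 of 129 Hnf4 sites and 150 of 548 TATCGATA sites.

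Promoter peaks were more frequent at genes of fatty acid oxidation, glycolysis, peroxisomes and the ribosome, and less frequent at germ line, digestive enzyme and cuticle genes. A total of 3207 protein-coding genes had an optimal summit within 1000 bp of a TSS, out of 5798 with any relaxed summit there. In the main tests, list counts are of members among these 5798, and members with no relaxed summit there are left out. Over 21 gene lists, 6 had more members with a peak than the other genes of this background and 3 had fewer, by Fisher's exact test with Benjamini-Hochberg adjustment at 0.05. Neighbouring genes can share a peak, so these p-values are too small by an unknown amount, and calls that other settings ended are named with their list.

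Fatty acid oxidation genes had a promoter peak in 18 of 22 members, 81.8% against 55.2% of other genes (adjusted p = 0.0451 by Fisher's exact test). The call held in 10 of 11 alternatives, with adjusted p from 3.11e-05 to 0.0676, the highest from a Wald test with TSS number as a covariate. After yip2, the strongest were Acadvl (FBgn0034432), for a very-long-chain acyl-CoA dehydrogenase, at 646, Mtpalpha (FBgn0028479), for a subunit of the mitochondrial trifunctional protein, at 584, and Mcad (FBgn0035811), for medium-chain acyl-CoA dehydrogenase, at 474. The Mtpalpha peak lay at 2L 9576175 to 9576945 and held both Hnf4 motifs. Acox3 had a relaxed region but no optimal peak at a promoter. The glycolysis and glucose list had a peak at 15 of 16 members (exact test, adjusted p = 0.00846). Its strongest were Gapdh2 (FBgn0001092), for a glycolytic dehydrogenase, at 1082, Hex-A at 366, Eno at 362 and Ldh at 274. Of all 23 annotated members of that list 8 had no promoter peak. AGBE and Gapdh1, among these, had no relaxed region there and lie outside the 16. The glycolysis call held in 7 of 11 alternatives, with adjusted p from 9.41e-05 to 0.254. It ended without replicate 2, at 75.0% of members (exact test, adjusted p = 0.254), and in the strongest 50% of optimal peaks, at 56.2%.

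Ribosomal protein genes had the lowest p of the 21 lists, with peaks at 56 of 58 members, 96.6% against 54.9% (Fisher's exact test, adjusted p = 3.72e-11), and the call held in all 11 alternatives. RpL34b at 499, RpL7 at 449, RpL32 at 425 and RpS20 at 330 were the strongest. Of all 88 annotated members 32 had no promoter peak. RpL10Aa and RpL13A, among these, had no relaxed region there and lie outside the 58. All 7 peroxisome genes in the background had a peak (exact test, adjusted p = 0.0451), led by Pex10, for a peroxisome biogenesis factor, at 286 and Pex2 at 179. Of all 15 annotated peroxisome members 8 had no promoter peak. The peroxisome call held in 4 of 10 alternatives, with adjusted p from 0.00882 to 0.397 by exact or likelihood ratio tests. It ended without replicate 1 (odds ratio 7.79, adjusted p = 0.0595, exact test) and without replicate 2 (odds ratio 7.42, adjusted p = 0.0716, exact test), with a peak at 9 of 10 members in each.

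All 10 background members of a list of candidate Hnf4 targets drawn up before the data were examined had a peak (exact test, adjusted p = 0.0124). This list shares 7 genes with the fatty acid oxidation list, so the counts are not independent. Its members were yip2, Mtpalpha and Mcad as above, whd, for carnitine palmitoyltransferase, at 337, scu at 289, Hnf4 at 262, the lipase gene bmm at 174, Lip3 at 150, Acsl at 147 and CPT2 at 99.5. Cyp4g1, FASN2, FASN3, Gapdh1 and Hex-C had no peak and no relaxed region at a promoter. The call held in 9 of 10 alternatives, with adjusted p from 0.00128 to 0.161, and ended with a TSS window of 2000 bp, at 83.3% of members (exact test).

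The lists of germ line markers, digestive enzymes and cuticle proteins had fewer members with a peak. Germ line and testis markers had a peak at 1 of 13 genes, can, at 77.2 (adjusted p = 0.00846 by Fisher's exact test). Midgut digestive enzymes had none of 7 (exact test, adjusted p = 0.0124), and larval cuticle proteins none of 5 (exact test, adjusted p = 0.0451). These lists have 31 and 14 annotated members. Amy-d and Amy-p of the former and Acp1 and Cpr47Ea of the latter had no relaxed region at a promoter and lie outside these counts. The germ line call held in 8 of 11 alternatives, with adjusted p from 0.00101 to 0.473, and ended without replicate 2, at 33.3% of members (exact test, adjusted p = 0.473). The digestive enzyme call held in 6 of 10, with adjusted p from 0.00128 to 0.154, and ended without replicate 1, at 16.7% of members (exact test, adjusted p = 0.154). The cuticle call held in 5 of 10, with adjusted p from 0.0106 to 0.300, and ended without replicate 2, still at 0% of members (exact test, adjusted p = 0.0562). Neuron markers had a peak at 1 of 8 genes, elav, at 415, which did not pass (exact test, adjusted p = 0.0545), but did without replicate 2 (exact test, adjusted p = 0.0481; 0.0106 to 0.412 over 11 alternatives).

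The insulin and nutrient list had 12 of 14 members with a peak and did not pass the test (Fisher's exact test, adjusted p = 0.0545), with REPTOR at 713, bigmax at 363, InR at 339 and Thor at 289. It passed in 2 of 11 alternatives, against all protein-coding genes and with peaks supported by both replicates (adjusted p from 0.000848 to 0.412 over the 11, by exact, likelihood ratio or Wald tests). The remaining lists did not pass either, with adjusted p from 0.236 to 1. Nuclear respiratory chain genes had 12 of 17, with Cyt-c-p at 483, and tricarboxylic acid cycle genes 10 of 13, with Idh3g at 371. Lipid storage and synthesis had 12 of 16, with Lpin at 486, and passed without replicate 1, at 86.7% of members (exact test, adjusted p = 0.0493; 0.00338 to 0.744 over 11 alternatives). Long-chain hydrocarbon genes had 4 of 5, with Sc2 at 228. Fat body markers had 8 of 11, with sug at 362, and detoxification genes 8 of 11, with Keap1 at 328. Malpighian tubule and V-ATPase genes had 7 of 10, with Vha100-2 at 522. Midgut markers had 5 of 9, with Myo61F at 532, nuclear receptor and ecdysone genes 9 of 17, with ERR at 299, and muscle markers 4 of 7, with Zasp52 at 164.

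**Figure D3:**
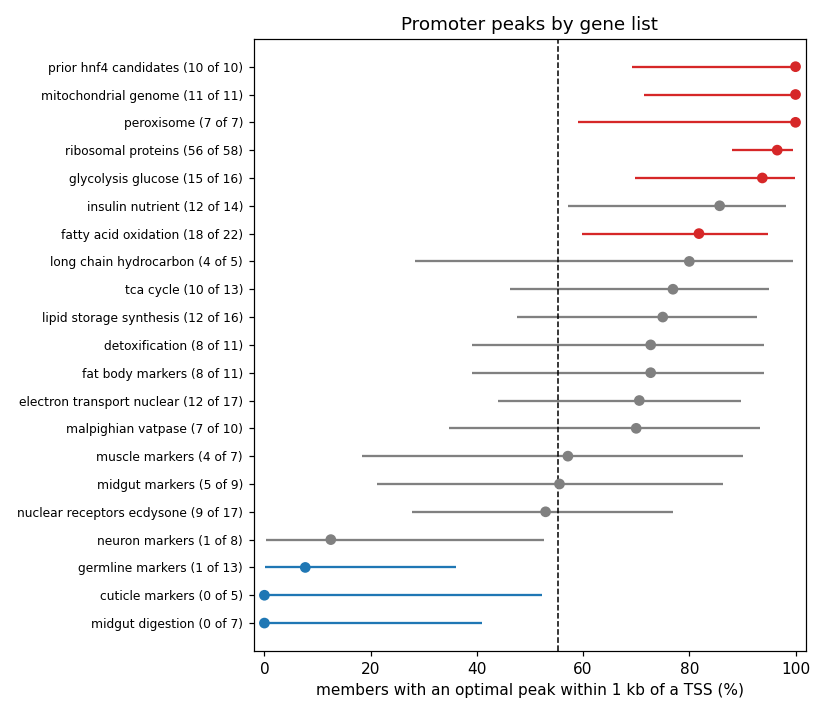
Percent of the background members of each gene list with an optimal summit within 1 kb of a TSS, with 95% exact binomial intervals. Red lists were higher and blue lists lower than other genes at an adjusted p under 0.05, grey lists did not pass, and the dashed line marks the 55.3% of all 5798 background genes.

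The mitochondrial chromosome carried the optimal peak with the highest signal value, but regions there were listed for replicate 1 and not for replicate 2. The signal value of this peak is from the pooled replicates, and replicate 1 gave 2421 there. The absence of a listed region in replicate 2 does not show that it had no signal. Of the optimal peaks, 14 lay on this chromosome, the first at positions 1387 to 2232 with its summit in the coding exon of mt:CoI (FBgn0013674), for cytochrome c oxidase subunit I, with a signal value of 3161. All 11 mitochondrial protein genes in the background had a peak (Fisher's exact test, adjusted p = 0.00846). These neighbouring genes share peaks and are not independent: the peak at 3588 to 3752 counts for mt:CoII, mt:ATPase8 and mt:ATPase6. The dm6 list of replicate 1 had 29 mitochondrial regions and that of replicate 2 had 0. In the dm3 lists, replicate 1 had 7, replicate 2 had 0 and the optimal set had 0. With no region in replicate 2, none of these genes could have a peak supported by both replicates, and without replicate 1 there was no value for them.

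Hnf4 itself (FBgn0004914, 2L 8687226 to 8709611, minus strand) had several peaks. The gene and 20 kb on either side held 11 optimal peaks, 7 of them inside the gene. The strongest, at 2L 8692435 to 8692712 in an intron 209 bp from a TSS, had a signal value of 262 and was number 761 of all optimal peaks, with 164 in replicate 1 and 106 in replicate 2. Replicate 1 had 50 regions in this window and replicate 2 had 34. The labels describe a transgenic line, and an extra copy of this locus could add to these values, unless the control held it too.

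**Figure D4:**
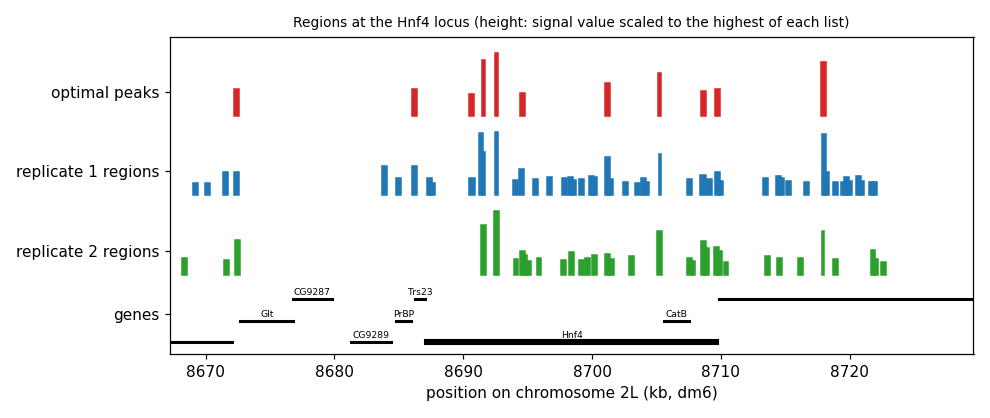
Map of the Hnf4 gene and 20 kb on either side on chromosome 2L (dm6, kb), with optimal peaks and the regions of each replicate as bars and protein-coding genes as black lines. Bar height follows the signal value scaled to the highest of each list, and 7 of the 11 optimal peaks lie inside Hnf4.

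Optimal peaks were spread over the chromosome arms at 39.9 to 48.4 per Mb, except on chromosome 4 with 28.2 per Mb. Chromosome 4 held 0.655% of optimal peaks against 2.71% of weaker regions (odds ratio 0.237, Fisher's exact test, adjusted p = 1.93e-25). Weaker regions were dense there, at 464 per Mb against 144 to 195 on the other arms, so the odds ratio reflects both densities. The share was also lower on 3L (21.2% against 23.7%, exact test, adjusted p = 0.000139) and higher on 2R (17.4% against 15.7%, adjusted p = 0.00433) and 3R (23.4% against 21.6%, adjusted p = 0.00433). X and 2L did not pass, with adjusted p of 0.264 and 0.491. The 3R difference ended in the strongest 50% of optimal peaks (exact test, adjusted p = 0.450).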

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

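All tests of explanations here were chosen after the results were seen. In dm3, 6 optimal peaks lay on heterochromatic or unplaced sequences, which no comparison used: 2 on 3LHet, 1 on XHet and 3 on Uextra.

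The optimal peak with the highest signal value was mitochondrial, yet 0 of the 14 mitochondrial peaks had a region in replicate 2, against 97.8% of nuclear optimal peaks. This leaves Hnf4 binding in both replicates open, since replicate 2 lists no region of that chromosome in either build, which handling of the chromosome could also give. Neither Hnf4 motif occurs on that chromosome. A difference in processing between builds may contribute: the highest mitochondrial signal value of replicate 1 in dm3 was 3.91% of that in dm6, while the list medians were at 97.7%. More mitochondrial DNA in replicate 1 than in the control stays open, since replicate 1 regions covered 48.4% of the chromosome, neither nearly all nor little of it. Binding in replicate 1 alone was not tested, and no biological explanation was, as the design has 1 group.

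The cluster at Hnf4 could come from an extra copy of the locus in the transgenic line. Relaxed regions outside the optimal set numbered 30 there against a median of 8 in 2122 windows of the same size, at the 94.7th percentile, and 113 windows held as many or more. Optimal peaks numbered 11 against a median of 2, and 71 windows held as many or more. An extra copy cannot be told apart from Hnf4 binding at its own gene, because no untagged or input values were analysed here. Of the 11 optimal peaks there, 1 held an Hnf4 motif, inside the Hnf4 gene but nearest to the TSS of CatB, 332 bp away.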

How the results depend on the processing

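Some alternatives were chosen after seeing the data: 1 mismatch in the Hnf4 site, lists without the mitochondrial chromosome or from peaks strong in both replicates, the Wald test, and motifs by promoter location. Replicate overlap stayed above chance in every alternative run (57.7 to 74.7%). The promoter share (43.8 to 64.7%, odds ratios 2.51 to 4.42) and the Hnf4 motif share (0.688 to 7.84%) stayed above background. The motif's odds ratio went from 2.84 to 1.29 with 1 mismatch (7.84% against 6.18%) and was 2.02 to 3.57 otherwise. With each replicate left out in turn the promoter share was 54.3 to 56.6%, the motif share 0.791 to 1.10%, the enriched lists 4 to 5 and the depleted lists 2. Read depth is unknown, so its limits could not be set. No paired analysis was possible because there is 1 group.

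The peak number was 2849 with 50% reciprocal overlap in both replicates, by construction. Mitochondrial peaks went from 14 to 0 in dm3, and peaks at the Hnf4 locus, whichever gene they were nearest to, from 11 to 7 in the gene body alone. Depleted lists went from 3 to 1 in the strongest 50% and 1 against all protein-coding genes, where enriched lists went from 6 to 9, with the insulin, lipid storage, fat body and tricarboxylic acid lists added and peroxisomes lost. With TSS number as covariate, the Wald test, which was run first, gave 1 enriched and 0 depleted of 16 lists, having no value for lists with all or no members bound; the likelihood ratio test that replaced it after this was seen gave 6 and 4 of 21.

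Reversed lists were uncalled ones except mitochondrial genes, at 0% with peaks strong in both replicates, by construction, as replicate 2 has no region there. Midgut markers reversed at 11.1% (strongest 50%), 22.2% (strong in both, and without replicate 1; 75.0% without replicate 2, not reversed) and 55.6% (both covariate tests). Muscle markers reversed at 14.3% (strongest 50%), 40.0% and 37.5% (without replicate 1 and 2), 44.4% (2000 bp), 36.4% (nearest TSS), 20% (all genes), 57.1% (both covariate tests) and 28.6% (strong in both). Nuclear receptors reversed at 61.1% (without replicate 2; 47.6% without replicate 1), 63.2% (2000 bp), 37.5% (all genes) and 85.0% (nearest TSS), where they became higher (exact test, adjusted p = 0.0121; 0.0121 to 1 over 11 alternatives). Outside promoters TATCGATA (0.484%) and C/EBP (0.484%) reversed, and at promoters CREB (0.511%), while GATA and M1BP lost their calls outside them. The cause was not tested. Of other list results 24 lost and 10 gained a call, and of 89 named genes 81 kept a peak without replicate 1 and 88 without replicate 2.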

Other observations

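The tests in this part were all chosen after the results were seen. Among genes with an optimal promoter peak, 7 of the 18 fatty acid oxidation genes had an Hnf4 motif under one, 38.9% against 1.38% of other genes (Fisher's exact test, adjusted p = 8.91e-08 over 19 lists). The genes, some named only after this was seen, were yip2, Mtpalpha, Mtpbeta, scu, whd, CPT2 and Acox57D-d. The share was 36.4% in the strongest regions of replicate 1 alone and 27.3% in those of replicate 2. The promoter sequences of this list held a motif in 15 of 28 genes, 53.6% against 5.03% of other genes, whether or not a peak was there. Of these 15, 12 had an optimal promoter peak, against 18 of all 28 members. Whether members with a motif had a peak more often was not tested. Of the other 18 lists, candidate targets, which share 7 genes with this one, also passed (5 of 10, exact test, adjusted p = 1.88e-06), as did fat body markers (2 of 8, exact test, adjusted p = 0.0414). Ribosomal protein genes had a motif at 1 of 56.

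Gene families grouped by symbol gave 3 higher and 10 lower of 79 (Fisher's exact test with Benjamini-Hochberg adjustment at 0.05). The higher ones were RpL (31 of 31), RpS (25 of 27) and mRpL (18 of 21). Odorant receptors (0 of 11) and gustatory receptors (0 of 10) were among the lower ones, with adjusted p of 0.00369 and 0.00577. Against all protein-coding genes, RpL, RpS and both receptor families kept their calls. The mRpL call ended there (18 of 47, Fisher's exact test, adjusted p = 0.102), as did those of the lower families Eig, Sfp, lectin, yellow and CheB. In that setting the families pre and Cul became higher and Ir lower.

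Of optimal peaks 53.8% lay at promoters, and TATCGATA was in 7.09% of these against 2.16% of weaker promoter regions. The share of promoter peaks with any core promoter motif was not counted. CAAAGTCCA, exact or with 1 mismatch, under most peaks is argued against, since 7.84% of optimal peaks held such a site (95% exact interval 7.16 to 8.56). Other forms of Hnf4 site are not covered by this count. Much of the 7.84% is background, as 6.18% of weaker regions held such a site too (odds ratio 1.29), and the site written backwards was at 4.35% against 3.97%. Promoter signal that does not depend on Hnf4 sites stays open, since 0.958% of promoter peaks held the exact site, more than weaker promoter regions but too few to speak for the others. More degenerate sites, recruitment by other factors and signal that any antibody would give at active promoters stay open and were not tested. No biological explanation was tested, as the design has 1 group.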
